A study of Mus musculus with 4 samples.

How the data were processed

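The data are chromatin immunoprecipitation sequencing (ChIP-seq) of H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, in the left cerebral cortex of adult female mice aged 2 months. The animals belonged to the strain B6CASTF1/J, a first-generation cross of C57BL/6J and CAST/EiJ. Per the labels, the 4 samples form 1 group of 2 pools, called pool I and pool J, each made from 4 biosamples, and each pool was sequenced as 2 technical libraries. The series gives no second tissue, treatment or untreated group, so no contrast between conditions was tested.

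The authors deposited 4 peak lists on mm10, the mouse assembly also known as GRCm38. Per the file descriptions, a replicated list and a pseudoreplicated list were made from the alignments of both pools, and 1 pseudoreplicated list was made from the alignment of each pool alone. How these lists were made is not given in more detail in the sources used here, and a replicated peak need not overlap a peak in the list of each pool alone (40346 of 72027 did). The 2 technical libraries of a pool share 1 filtered alignment, so values exist per pool and not per library. The aligner, the peak caller, their versions and the treatment of strain variants are not given in the sources used here. Reads from the CAST/EiJ copy of the genome differ from the reference sequence at strain variants, which could lower their count in a way these lists do not show.

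Each deposited list has 10 columns in narrowPeak format. The signal of each peak is the value the authors' peak caller gave, and its normalization is not given in the sources used here. The authors also gave the −log10 p and −log10 q of each peak against its background, and the place of its summit. These values were used only to describe, rank or filter peaks within a list, and a rank in a list of one length shows no change against a rank in a list of another length. Signal tracks named in the file descriptions were not used here. The number of reads per library is not given in the lists, so the depth is unknown and no interval for counting error was made from it.

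Genes came from the GENCODE vM21 basic annotation of GRCm38.p6, and the genome sequence was that of the same assembly. The basic set, in place of the full set of transcripts, was chosen here. The analysis covered 19 autosomes and the X chromosome, with 34568 protein-coding and long non-coding genes, of which 21755 were protein-coding, and 55728 transcription start sites (TSSs). Coordinates are given 1-based on mm10. A promoter peak overlapped the 1000 bp on either side of any annotated TSS of the gene. Such a peak counted for every gene whose TSS it lay near, so its signal need not be the gene's own. Every other peak was called distal and was assigned to the protein-coding gene with the nearest TSS within 100 kb, which names a neighbour and not a target. Peaks in 2 lists were matched where they overlapped by at least 1 bp, and the chance overlap came from 100 random placements of each peak on its own chromosome. Location classes were promoter, exon, intron and intergenic, in that order, against 100 random placements.

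The gene lists were fixed before the data were examined, together with the tests, the rule for naming genes and most alternatives. They are 36 lists of cell type markers, gene functions and genes of other tissues, and every one of their symbols was found in the annotation. Members with a promoter peak were compared with all other protein-coding genes by a two-sided Fisher's exact test, with 0.5 added to each count in the odds. Mean numbers of distal peaks were compared with 100000 random gene sets matched on the decile of territory length, the stretch of genome within 100 kb that lies nearest to the gene's TSSs, and drawn with replacement within a decile. The median rank of promoter signal was compared with 100000 random sets of genes with a promoter peak, for the 26 lists with at least 3 such members, and a gene took its highest promoter peak. Both permutation tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the lists of each test, and an adjusted p under 0.05 was called. All of these tests run across genes of 1 list and not across animals, neighbouring genes such as those of a Hox cluster are not independent, and the p-values say nothing of the spread between mice.

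Distal peaks within 12500 bp of each other were joined into stitched domains and ranked by signal times width, summed over peaks. Domains above the point where the scaled rank curve reaches a slope of 1 were called large, and the members of each list near a large domain were compared with other genes near any domain by Fisher's exact test. Its effect is given as a difference in shares, a form chosen after the data were seen because odds from lists with no member near a large domain took the wrong sign. Consensus matches of 16 motifs within 100 bp of the summits of distal peaks were compared with a flank 1000 to 1200 bp away in the same locus by McNemar's exact test, adjusted over the 16 motifs. Shares of genes carry 95% Clopper-Pearson intervals.

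Genes are named by rule. For each list, these are the 3 members with the highest promoter signal and, where fewer than 9 in 10 members have a promoter peak, the first 2 in alphabetical order without one. Added to these are the genes at the 10 widest and the 10 highest promoter peaks, the 10 genes with the most distal peaks, the nearest protein-coding genes of the 10 top domains, and the genes nearest to the 3 highest peaks of each pool alone. Some genes that this rule names are not reported here. Other genes named in the text were chosen after their values were seen, and this holds for the members given for a list beyond its first 3.

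Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The tests were tested on simulated data for the 21755 genes, with 200 simulated lists of 18 genes per setting. Without a difference, the promoter test gave a p under 0.05 in 4% of lists, the distal test in 4% and the signal test in 4.5%. The promoter test detected 97% of lists with a promoter share of 95% and 99.5% of lists with a share of 10%. The distal test detected 45.5% of lists with 2 times the peaks and 69% with 3 times. The signal test detected 83.5% of lists raised by 30 percentile points. Detection here means an unadjusted p under 0.05, so at the adjusted threshold these shares can only be the same or lower. Smaller lists were not simulated.

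Each result was recomputed with 1 choice changed at a time, except where a pool was left out. The alternatives were a −log10 q of at least 5, the peaks at or above the median signal, promoter windows of 500 and 2500 bp and the gene's 5′ end alone. Others were distances of 50 and 250 kb, summed distal length, joining of domains within 5000 bp or not at all, and promoter peaks kept in domains. Width or −log10 p stood in place of signal, and the summit in place of the interval. Overlap was made stricter, at least 50%, and lists were extended by 500 bp or intervals within 1000 bp joined. The set was also limited to only genes with a peak. Motif windows were changed, and flanks held to a GC content within 5 percentage points. The pseudoreplicated list of both pools was used as well. Leaving out a pool means using the pseudoreplicated list of the other pool in place of the replicated list, so that pool and kind of list change together and a call that ends there cannot be put down to the pool alone. Beside 54 alternatives, 2 were added after seeing the data, and both match genes on the CpG content of their promoters. A single pool I peak on the Y chromosome was left out of all tests.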

Results

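H3K27ac was mapped in the left cerebral cortex of female B6CASTF1/J mice in 2 pools, I and J, which together make up the 4 samples and the only group. Among the widest promoter peaks of the replicated list were those of Tcf4, Bcl11a and Zbtb18, transcription factor genes of the developing cortex, with 16348, 11773 and 10807 bp. No peak of the pool J list was this wide, since its widest had 9904 bp. The replicated list held 72027 peaks with a median width of 597 bp, which covered 62.8 Mb or 2.38% of the genome. A −log10 q of at least 5 was reached by 53.6% of them, and 7.84% were 2 kb or wider. The pseudoreplicated list of both pools held 76359 peaks, that of pool I 69835 and that of pool J 49839. The pool I list had 1.40 times as many peaks as the pool J list, 1.81 times the covered length and 1.26 times the median width. Each pool gave a single list, so these ratios have no error, and the depth behind them is unknown.

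Nearly all regions found in pool J were also found in pool I. Of the pool J peaks, 93.1% overlapped a pool I peak, against 4.91% ± 0.0896 (mean ± SD of 100 random placements), and of the pool I peaks 55.5% overlapped a pool J peak, against 3.31% ± 0.0575. Of the 72027 replicated peaks, 40346 lay in the lists of both pools, 18914 in that of pool I alone, 2730 in that of pool J alone and 10037 in neither. Peaks in both had a median signal of 5.04 and a median width of 941 bp, and peaks in neither had 2.67 and 269 bp. Over 37394 matched peaks the signal of pool I and pool J was correlated with a Spearman rho of 0.811 and, for log2 signal, a Pearson r of 0.855. These coefficients run across peaks, which are not independent replicates. When the overlap had to reach 50% of both peaks, 50.2% of the pool J peaks were matched, and 91.7% when it had to reach 50% of the shorter peak alone. Reciprocal overlap also falls where peaks differ in width, as they did between the pools.

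The regions of 1 pool alone were low in its own ranking. The 31099 pool I peaks without a match in pool J had a median signal percentile of 25.8, and 0 were in the top decile of the pool I list. Of these, 9.75% overlapped a promoter, against 41.3% of the matched ones. The highest lay nearest to the coding gene 6030408B16Rik (chromosome 15, 101311493–101312070, signal 9.62), in the neighbourhood of Kcnma1, which encodes a calcium-activated potassium channel (chromosome 14, 23593512–23594735, signal 9.23), and at the promoter of Mthfs, an enzyme of folate metabolism (chromosome 9, 89210364–89210976, signal 9.21). The 3448 pool J peaks without a match in pool I had a median percentile of 18.4, and 1 was in the top decile. The highest lay at the promoters of Usp31 (chromosome 7, 121707149–121707461, signal 9.46), Tlk1, a chromatin kinase (chromosome 2, 70825544–70825776, signal 7.79), and Atxn2, an RNA-binding protein (chromosome 5, 121711798–121712048, signal 6.31). All 6 regions overlapped a peak of the replicated list. With both lists extended by 500 bp, 21735 pool I and 1665 pool J peaks had no match, with 0 in the top decile of either list. The Usp31 peak, the 1 pool J peak in the top decile, thus had a match in pool I at that distance. At a −log10 q of at least 5 in both lists, 24695 pool I and 1172 pool J peaks had no match.

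Promoters held far more peaks than random placement gave. Of the replicated peaks 27.4% overlapped a promoter, against 4.37% ± 0.0687 (mean ± SD of 100 placements, 6.27-fold). Exons away from promoters held 4.24% (1.45-fold) and introns 48.4% (1.16-fold), while 20.0% were intergenic (0.392-fold). Each class differed from placement with a permutation p of 0.0099, the smallest that 100 placements can give. The promoter share was 27.3% in the pool I list and 35.6% in the pool J list. Introns turned from more to fewer peaks than placement at a −log10 q of at least 5 (36.3%, 0.876-fold). The promoter share at that threshold was 42.7%, against 4.87% for placement. A peak counted in 1 class only and promoters came first, so a larger promoter share lowers the other shares. The exon, intron and intergenic folds thus do not show how peaks away from promoters were spread.

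**Figure D1:**
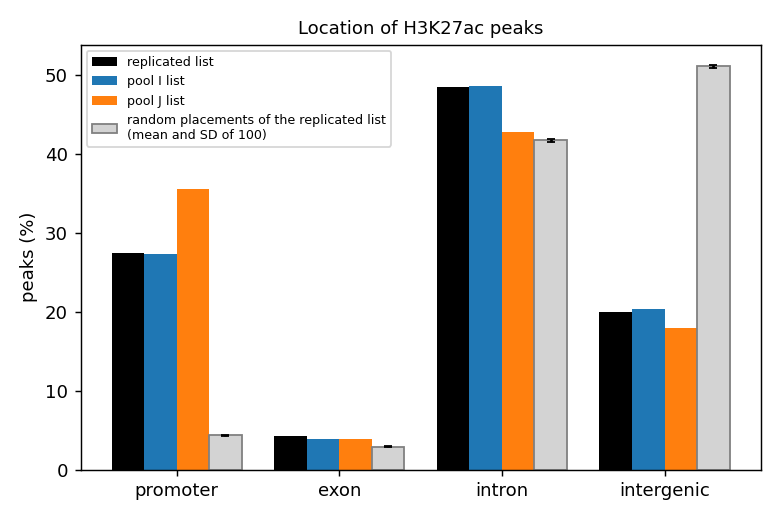
Share of H3K27ac peaks (%) that fell in promoters, exons, introns and intergenic sequence in the replicated, pool I and pool J lists, with the mean and SD of 100 random placements of the replicated list in grey. Promoter shares were 27.4%, 27.3% and 35.6% against 4.37% for placement.

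Of the 21755 protein-coding genes, 12719 had a promoter peak in the replicated list (58.5%, 95% Clopper-Pearson interval 57.8 to 59.1%). The share was 58.2% with the pool I list and 55.2% with the pool J list, and 11906 genes had a promoter peak in both pools, 766 in pool I alone, 99 in pool J alone and 8984 in neither. The interval covers sampling of genes only and not the spread between mice.

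Genes of excitatory neurons and synapses carried promoter H3K27ac without exception in the lists tested. All 18 excitatory neuron markers had a promoter peak, among them the NMDA receptor gene Grin2b (signal 15.7) and the muscarinic receptor gene Chrm1 (signal 15.0). So did all 18 presynaptic genes, among them the synaptic vesicle genes Vamp2 (signal 25.9) and Rab3a (signal 22.4), and all 16 postsynaptic genes, led by the scaffold gene Lrrc7 (signal 17.3), Grin1 (signal 17.1) and Dlgap3 (signal 16.5). All 15 voltage-gated channel genes had one, with Kcna2 (signal 18), Kcna1 (signal 17.7) and Kcnma1 (signal 16.2) the highest. Against other coding genes the log2 odds were 4.72 for the excitatory and the presynaptic list, 4.55 for the postsynaptic and 4.46 for the channel list (Fisher's exact test, adjusted p over 36 lists 0.000388, 0.000388, 0.000565 and 0.000881). The counts were complete in the list of either pool as well. With the gene's 5′ end alone, the channel list was not called (log2 odds 1.5, adjusted p 0.0985, Fisher's exact test).

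The same held for genes switched on by neuronal activity, clock genes and genes needed in every cell. All 20 activity-regulated genes had a promoter peak, among them the AP-1 genes Jund (signal 22.3), Junb (signal 18.7) and Fosl2 (signal 18.5), as did all 16 circadian clock genes, led by the nuclear receptors Nr1d2 (signal 29.2) and Nr1d1 (signal 21.1) and by Per1 (signal 19.6). All 18 housekeeping genes had one, with the actin gene Actb at a signal of 31.3 and Ywhaz at 18.6, and all 16 genes of oxidative phosphorylation, with Atp5c1 at 23.8, Ndufa4 at 20.2 and Ndufs1 at 19.4. Their log2 odds lay between 4.55 and 4.87 (Fisher's exact test, adjusted p from 0.000223 to 0.000565 over 36 lists), and the counts were complete in either pool. All 11 heat shock and stress genes had one too (log2 odds 4.03, adjusted p 0.00714, Fisher's exact test), with Atf4 at 30.7, the chaperone Hsp90aa1 at 20.0 and Hspa8 at 19.4. In the pool J list 8 of these 11 had one, and the heat shock list was not called (log2 odds 0.98, adjusted p 0.424), nor was it with the gene's 5′ end alone (1.59, 0.169) or at a −log10 q of at least 5 (1.65, 0.162, Fisher's exact tests).

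Markers of cortical layers and astrocytes were also marked more often than other genes in the replicated list. Of 16 upper layer markers 14 had a promoter peak (log2 odds 2.04, adjusted p 0.0296), with Pou3f3 (signal 13.0), Lhx2 (signal 9.82) and Cux1 (signal 9.56) the highest and Otof and Scnn1a without one. Of 18 deep layer markers 16 had one (log2 odds 2.23, adjusted p 0.0127), with Tle4 (signal 14.2), Etv1 (signal 12.9) and Nfia (signal 8.06) the highest and Cplx3 and Nxph4 without. Of 20 astrocyte markers 18 had one (log2 odds 2.40, adjusted p 0.00887), led by Clu (signal 19.8), the glutamate transporter gene Slc1a2 (signal 13.8) and Glul (signal 8.02). Of 19 endothelial markers 16 had one (log2 odds 1.75, adjusted p 0.0459), led by the glucose transporter gene Slc2a1 (signal 16.7), Erg (signal 5.45) and Mfsd2a (signal 4.95), while Abcb1a and Foxq1 had none. All 4 are Fisher's exact tests over 36 lists, and all 4 lost their call without pool I, that is in the pseudoreplicated list of pool J, with log2 odds of 1.65 (adjusted p 0.0625) for upper layers, 1.00 (0.209) for deep layers, 1.2 (0.151) for astrocytes and 0.44 (0.704) for endothelial cells. The endothelial call was also lost without pool J (log2 odds 1.31, adjusted p 0.123), with the gene's 5′ end alone (1.06, 0.212) and with the list of both pools (1.29, 0.125), and the upper layer call with the 500 bp window (1.5, 0.100). At a −log10 q of at least 5 all 4 calls ended, with log2 odds of 1.67 (adjusted p 0.0615) for upper layers, 1.02 (0.199) for deep layers, 1.22 (0.101) for astrocytes and −0.72 (0.378, Fisher's exact tests) for endothelial cells.

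Several other cell types of the cortex did not pass the promoter test with the 1000 bp window in the replicated list. Of 24 interneuron markers 16 had a promoter peak (log2 odds 0.46, adjusted p 0.567), with Cnr1 (signal 11.7), Satb1 (signal 10.1) and Kcnc2 (signal 8.56) the highest and Adarb2 and Calb2 among those without. Of 20 oligodendrocyte markers 15 had one (log2 odds 1.00, adjusted p 0.204), led by the myelin gene Mbp (signal 10.3), Cnp (signal 7.01) and Fa2h (signal 5.56), with Ermn and Mobp unmarked. With the 2500 bp window 18 of the 20 oligodendrocyte markers had one, which was called (log2 odds 2.31, adjusted p 0.00840, Fisher's exact test). Of 14 oligodendrocyte precursor markers 6 had one (log2 odds −0.88, adjusted p 0.317), led by Tnr (signal 13.5), Cspg5 (signal 12.9) and Bcan (signal 8.06), with Bmp4 and C1ql1 unmarked. Of 20 microglia markers 10 had one (log2 odds −0.49, adjusted p 0.545), among them Sall1 (signal 7.66) and Aif1 (signal 5.46), with the complement genes C1qa and C1qb unmarked. In the pool J list 6 of 20 microglia markers had one, which was fewer than other genes (log2 odds −1.46, adjusted p 0.0402, Fisher's exact test over 36 lists, as are those above). Of 14 neurogenesis and proliferation genes 7 had one (log2 odds −0.49, adjusted p 0.609), among them the Notch target Hes5 (signal 15.4) and Sox11 (signal 8.86), with the mitotic genes Bub1 and Ccnb1 unmarked.

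The lists of other tissues, the hindbrain and midbrain and the hypothalamus were marked less often than other genes. No promoter peak was found at any of the 39 Hox genes, which pattern the body axis behind the forebrain (log2 odds −6.80, adjusted p 2.25e-14), at the 12 lymphoid and granulocyte genes such as Cd3d (log2 odds −5.14, adjusted p 0.000223) or at the 9 pluripotency genes such as Dppa3 and Dppa5a (log2 odds −4.74, adjusted p 0.000881). Of 20 midbrain and hindbrain genes only Cbln3 had one (signal 8.56), and Atoh1 and Barhl1 were among the 19 without (log2 odds −4.20, adjusted p 8.09e-06). Of 14 liver genes only Apob had one (signal 2.87), and of 14 germline genes only Dazl (signal 4.37), and Ahsg, Alb, Ddx4 and Dmrt1 had none (both log2 odds −3.66, adjusted p 0.000388). Of 15 striated muscle genes Myh7 (signal 3.57) and Acta1 (signal 2.97) had one (log2 odds −2.93, adjusted p 0.00159), with Actc1 and Ckm unmarked. Of 13 hypothalamic genes Agrp (signal 18), Ghrh (signal 7.36) and Hcrt (signal 4.62) had one (log2 odds −2.08, adjusted p 0.0296), and the hormone genes Avp and Crh did not. Of 1466 olfactory and vomeronasal receptor genes 11 had one (0.750%, log2 odds −7.73), with Vmn1r4 (signal 14.6), Olfr464 (signal 5.26) and Olfr459 (signal 4.89) the highest and Olfr1 and Olfr10 among those without. These are Fisher's exact tests adjusted over 36 lists. Absence from a peak list is not absence of acetylation, since the depth is unknown. A peak at a listed gene may also belong to the promoter of a neighbouring gene, which was not checked.

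Markers of pericytes and smooth muscle, and of cells that border or enter the tissue, had promoter peaks less often as well. Of 15 pericyte and smooth muscle markers 4 had a promoter peak (log2 odds −1.85, adjusted p 0.0260), led by Vtn (signal 9.46), Pdgfrb (signal 4.87) and Des (signal 4.17), with Abcc9 and Acta2 unmarked. Of 12 meningeal fibroblast markers Foxc1 (signal 2.77) and Col3a1 (signal 2.23) had one (log2 odds −2.57, adjusted p 0.00943), with Aldh1a2 and Col1a1 unmarked. Of 12 choroid plexus and ependymal markers only Dynlrb2 did (signal 6.06, log2 odds −3.43, adjusted p 0.00106), with Ak7 and the water channel gene Aqp1 unmarked, and of 10 erythroid genes only Klf1 (signal 4.16, log2 odds −3.16, adjusted p 0.00460), with Alas2 and Epb42 unmarked. These are Fisher's exact tests over 36 lists. At a −log10 q of at least 5 the pericyte list lost its call (log2 odds −1.64, adjusted p 0.0597), and it did so with the gene's 5′ end alone (−1.69, adjusted p 0.0536).

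Of the lists left, none was called with the 1000 bp window in the replicated list. Of 14 forebrain patterning factors 11 had a promoter peak (log2 odds 1.22, adjusted p 0.204), among them Nr2f1 (signal 14.1) and Zic2 (signal 9.16), with Lmx1a and Six3 unmarked. Of 14 striatal markers 9 had one (log2 odds 0.30, adjusted p 0.790), led by Foxp1 (signal 18.1) and Pde10a (signal 11.2), with the dopamine receptor gene Drd2 and Isl1 unmarked. Of 19 coding imprinted genes 15 had one (log2 odds 1.29, adjusted p 0.125), led by Blcap (signal 30.1), Impact (signal 20.9) and Ube3a (signal 17.6), with Dlk1 and Magel2 unmarked. Of 11 interferon response genes 3 had one (log2 odds −1.77, adjusted p 0.0815), among them Isg15 (signal 2.94) and Usp18 (signal 2.88), with Bst2 and Cxcl10 unmarked. In the pool J list 1 of the 11 had one, and the interferon list was called lower (log2 odds −3.11, adjusted p 0.00642, Fisher's exact test over 36 lists). It was also called lower at a −log10 q of at least 5 (−3.09, adjusted p 0.00688) and with the 2500 bp window (−1.86, adjusted p 0.0424), where imprinted genes were called higher (16 of 19, log2 odds 1.66, adjusted p 0.0424, Fisher's exact tests). In all, 13 of the 36 lists were called higher and 13 lower.

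**Figure D2:**
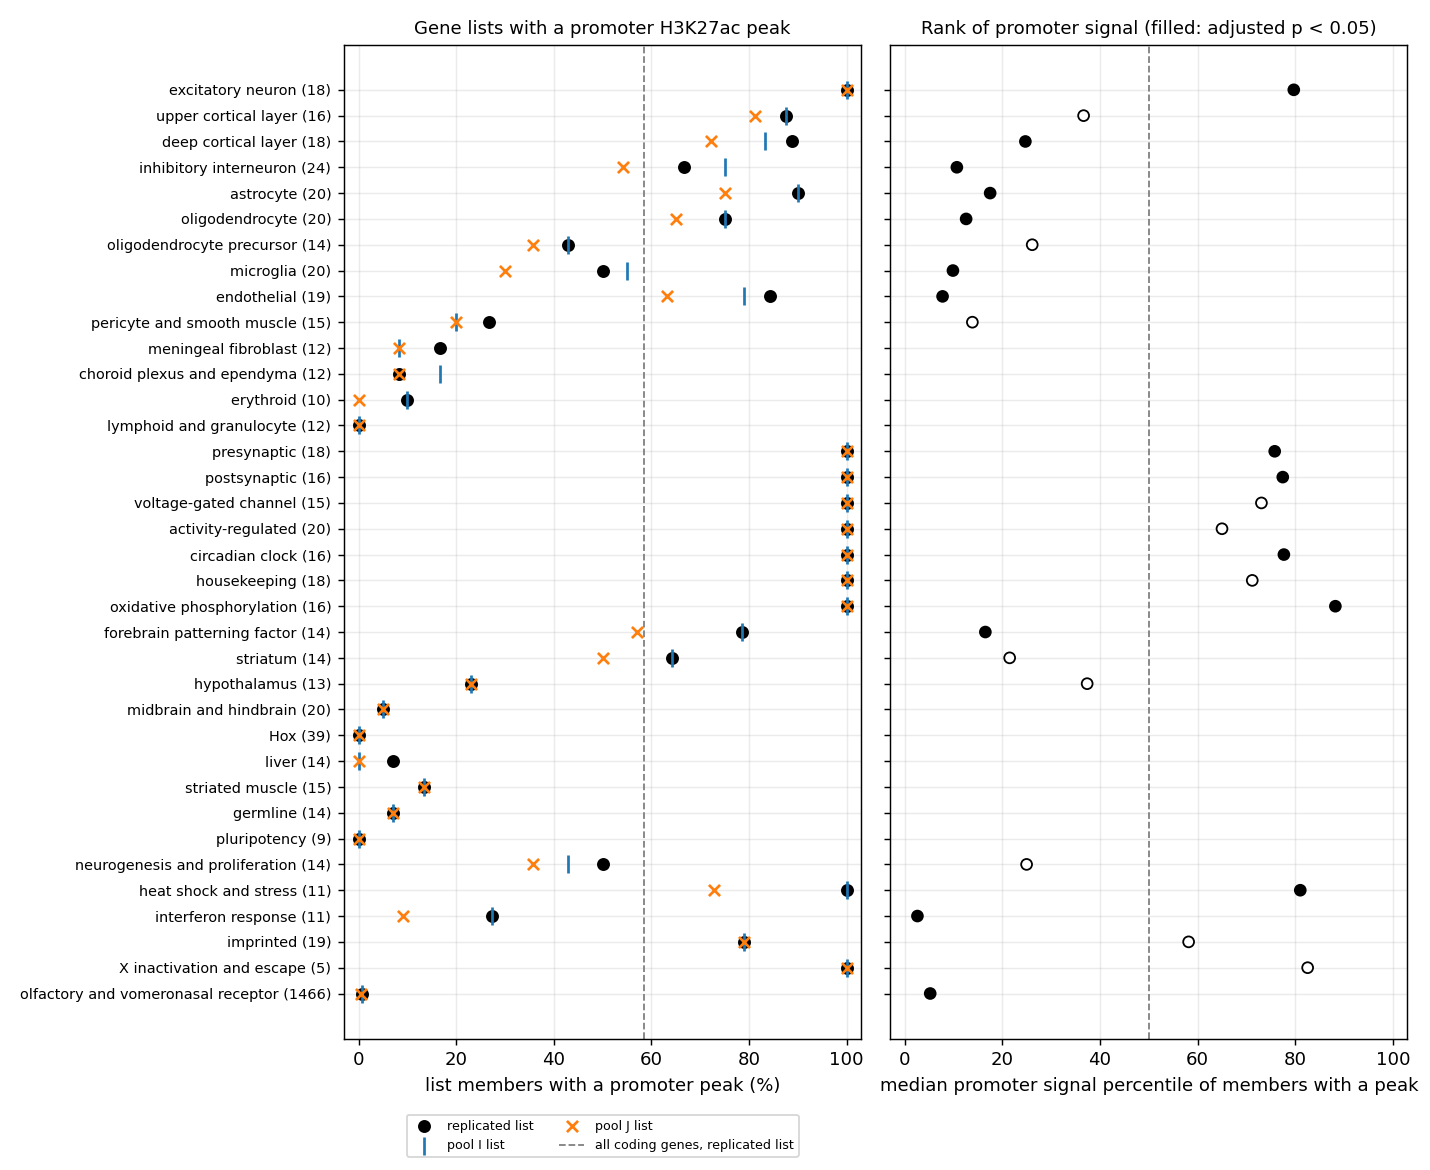
Left, share of the members of each gene list with a promoter peak (%) in the replicated, pool I and pool J lists, with the number of coding members in brackets and the share of all coding genes (58.5%) as a dashed line. Right, median promoter signal percentile of the members with a peak in the replicated list, against 50 for all such genes, filled where the permutation test was called (6 lists higher, 9 lower).

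Among genes with a promoter peak, 6 lists had higher signal than all such genes. The median percentile was 88.2 for the 16 genes of oxidative phosphorylation, 38.2 points above all genes with a promoter peak (adjusted p 0.000455), 79.7 for excitatory neuron markers (29.7 points, adjusted p 0.0114), 77.7 for clock genes (27.7 points, adjusted p 0.0257), 77.4 for postsynaptic genes (27.4 points, adjusted p 0.0263), 75.8 for presynaptic genes (25.8 points, adjusted p 0.0278) and 81.0 for heat shock genes (31 points, adjusted p 0.0349). These are permutation tests of 100000 random sets, adjusted over 26 lists. Leaving out pool I ended the call of the excitatory list (18.6 points, adjusted p 0.171) and the postsynaptic list (24.2 points, adjusted p 0.0759), and leaving out pool J that of the heat shock list (28.9 points, adjusted p 0.0540, permutation tests). Leaving out pool J also brought calls for activity-regulated genes, from 15.0 points (adjusted p 0.173) to 26.2 (adjusted p 0.0180), and housekeeping genes, from 21.2 points (adjusted p 0.0740) to 25 (adjusted p 0.0331, permutation tests). Activity-regulated genes were also called with the 2500 bp window (25.5 points, adjusted p 0.0244) and by width (36.4, 0.000208), and channel genes, at 23.1 points by signal (0.0746), by width (42.4, 0.000208, permutation tests).

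Marked promoters of interneuron, astrocyte, oligodendrocyte, microglia and endothelial markers ranked low. The median percentile was 7.74 for endothelial markers, such as Cldn5 of the blood-brain barrier (signal 4.17), with a difference from all genes with a promoter peak of −42.3 points (adjusted p 0.000260), and 10.7 for interneuron markers, such as the GABA synthesis genes Gad1 (signal 3.87) and Gad2 (signal 3.37), with a difference of −39.3 points (adjusted p 0.000433). It was 12.6 for oligodendrocyte markers (−37.4 points, adjusted p 0.00147), 9.87 for microglia markers (−40.2 points, adjusted p 0.00147) and 17.5 for astrocyte markers (−32.5 points, adjusted p 0.00397). The 11 forebrain patterning factors with a peak had a difference of −33.5 points (adjusted p 0.0245), the 16 deep layer markers −25.3 points (adjusted p 0.0388), the 3 interferon genes −47.4 points (adjusted p 0.0115) and the 11 receptor genes −44.8 points (adjusted p 0.000260). These are permutation tests over 26 lists. Cldn5, Gad1 and Gad2 lie outside the rule for naming genes and were chosen after their values were seen. In the pool J list the call ended for astrocytes (−26.7 points, adjusted p 0.0653), microglia (−30.4, 0.118), deep layers (−26.7, 0.0788) and patterning factors (−24.0, 0.174), and in the pool I list for deep layers (−18.1, 0.173) and patterning factors (−24.4, 0.112). When ranked by peak width, the astrocyte list stood at 15.1 points (adjusted p 0.277) and the heat shock list at −5.49 points (adjusted p 0.836, permutation tests), both turned in direction and not called. By width the calls also ended for oligodendrocytes (−11.2 points, adjusted p 0.512), microglia (−8.25, 0.704), patterning factors (−1.71, 0.945), deep layers (−7.80, 0.662) and oxidative phosphorylation (15.6, 0.277). The deep layer call ended with the 2500 bp window (−22.8, 0.0653) and at a −log10 q of at least 5 (−26.3, 0.0631), that of interferon genes with the 2500 bp window (−38.9, 0.0910) and that of receptor genes at the stricter q (−37.3, 0.0502, permutation tests). Lower calls were gained by oligodendrocyte precursors with the 2500 bp window (−41.0 points, adjusted p 0.0135), pericytes at the stricter q (−41.9, 0.0216) and striatum with the 500 bp window (−32.0, 0.0352, permutation tests).

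Matching genes on promoter CpG content, an alternative chosen after seeing the data, ended further calls of promoter signal. These were the lists of clock genes (24.0 points, adjusted p 0.0572), heat shock genes (29.6, 0.0572), deep layers (−22.9, 0.0842), astrocytes (−22.0, 0.0939), microglia (−24.4, 0.142), interferon genes (−39.8, 0.0939) and receptor genes (−24.8, 0.150). Voltage-gated channel genes gained a call (29.2 points, adjusted p 0.0413, permutation tests over 26 lists).

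The highest promoter peak was at Atp6v0c, a subunit of the vacuolar proton pump (chromosome 17, from 24168266, width 2536 bp, signal 41.8, with 45.4 in pool I and 36.6 in pool J). It was followed by Efcab2 (signal 36.2), the shared promoter of Arpc4 and Tada3 (35.2), Pcif1 (34.3), the shared promoter of Bud31 and Pdap1 (33.7), Brd2, a reader of acetylated histones, with H2-DMa (32), the receptor gene Gpr19 (31.5), the transcription factor gene Klf7 (31.4), Map7d1 (31.4) and Nfyc, a subunit of the CCAAT-binding factor NF-Y (31.3). Among the widest promoter peaks were those of Tcf4 (16348 bp), Bcl11a with A830031A19Rik (11773 bp), Zbtb18 (10807 bp), Sept8 (10692 bp), Mras (10561 bp), Elmo2 (10309 bp) and Sparcl1 (10021 bp). The widest peak of any kind had 25620 bp in the pool I list and 9904 bp in the pool J list, so none of these widths was reached in pool J. Widths between pools were not tested.

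Excitatory, synaptic, channel and activity-regulated genes also had more distal peaks than genes with territories of similar length. Postsynaptic genes had a mean of 11.9 distal peaks against 2.80 for matched sets (4.26-fold, adjusted p 0.0109), presynaptic genes 10.9 against 2.79 (3.92-fold, adjusted p 0.0109), excitatory neuron markers 11.9 against 3.23 (3.70-fold, adjusted p 0.0109), voltage-gated channel genes 15.8 against 4.66 (3.39-fold, adjusted p 0.0109) and activity-regulated genes 6.20 against 2.27 (2.74-fold, adjusted p 0.0398). Olfactory and vomeronasal receptor genes had 0.0546 against 0.955 (adjusted p 0.00036), and the other 30 lists were not called, among them upper layers (1.93-fold, adjusted p 0.170), deep layers (1.33-fold, 0.554) and interneurons (0.512-fold, 0.398). These are permutation tests of 100000 matched sets over 36 lists. The activity-regulated list lost its call without pool J (a difference of 3.22 peaks against 3.93, adjusted p 0.0584) and with assignment within 250 kb (3.71, adjusted p 0.125, permutation tests).

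The most distal peaks were nearest to Celf2, Kalrn and Tcf4. Celf2, an RNA-binding splicing factor, had 136, Kalrn, a regulator of dendritic spines, 132 and Tcf4 101. They were followed by Gm5136 (87), Kcnma1 (84), Anks1b (83), Prickle2 (76), the postsynaptic scaffold gene Dlgap1 (71), the calcium pump gene Atp2b2 (66) and Iqsec1 (63). In pool I the count was 144 for Celf2 and 108 for Kalrn, and in pool J 88 and 89. These counts rank genes within a list and carry no test.

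Joining distal peaks gave 18503 stitched domains, of which 497 were large (2.69%) and held 32% of the summed score. The first covered chromosome 14, 64097554–64457197, with 121 peaks, and 92.7% of it lay within Msra, a methionine sulfoxide reductase. It kept rank 1 in each pool. Others among the first 10 were nearest to 1700001O22Rik (chromosome 2, 30646566–30809885), the transcription factor gene Zeb2 (chromosome 2, 44995855–45109091) and G430095P16Rik (chromosome 8, 84698896–84797325, with 99.0% inside Nfix). Lower in rank came Gm5136 (chromosome 10, 108492572–108801185, with 98.4% inside Syt1, the calcium sensor of transmitter release), Pknox2 (chromosome 9, 36879028–37078531), Rbfox3, which encodes the neuronal protein NeuN (chromosome 11, 118738580–118901218), Ppara (chromosome 15, 85662791–85710193, outside any coding gene) and Grin2b (chromosome 6, 135785083–135960044). The Pknox2 domain (rank 7) ranked 14 in the pool I list and 38 in the pool J list, and the Gm5136 domain (rank 6) ranked 6 and 15. The Grin2b domain (rank 10) ranked 7 and 14, and the others named after the first lay between ranks 3 and 12 in either list. The number of large domains was 755 when peaks were joined within 5000 bp and 2230 without joining. Of the genes nearest to the first 50 domains, 29 were shared with joining within 5000 bp and 13 without joining. With the pool I and pool J lists 40 and 38 were shared.

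Large domains lay near excitatory, synaptic and clock genes more often than near other genes. Of 16 excitatory neuron markers near any domain, 6 were near a large one (37.5% against 5.33% of other genes, a difference of 32.2 percentage points, adjusted p 0.00430). The counts were 5 of 14 for postsynaptic genes (a difference of 30.4, adjusted p 0.0107), 5 of 16 for presynaptic genes (25.9, adjusted p 0.0142) and 4 of 12 for clock genes (28.0, adjusted p 0.0262). These are Fisher's exact tests over 36 lists, of which 4 were higher and 0 lower (6 and 0 at an unadjusted p under 0.05). Unlike the distal test they were not matched on territory length, so an effect of territory length on these shares cannot be told apart. In the pool I list, which differs from the replicated list in pool and in kind, the call ended for postsynaptic (a difference of 16.5, adjusted p 0.251), presynaptic (20.1, adjusted p 0.0804) and clock genes (25.8, adjusted p 0.0534), and in the pool J list for clock genes (13.4, adjusted p 0.572). The clock call also ended with joining within 5000 bp (21.8, adjusted p 0.0868), no joining (20.4, 0.304), summed width (19.1, 0.219) and the list of both pools (25.3, 0.0516), the presynaptic call with no joining (23.6, 0.119) and at a −log10 q of at least 5 (15.9, 0.254), and the postsynaptic call with the list of both pools (23.1, 0.0518, Fisher's exact tests). The postsynaptic and clock calls thus ended with the kind of list alone, before any pool was left out. Channel genes gained a call with joining within 5000 bp (26.6, adjusted p 0.0214), no joining (31.4, 0.0489) and promoter peaks kept (27.7, 0.00663), and activity-regulated genes with promoter peaks kept (39.4, 2.07e-05, Fisher's exact tests). The excitatory list alone was called under each of these alternatives, and 0 of 14 interneuron markers were near a large domain (adjusted p 1, Fisher's exact test).

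The X chromosome, of which females keep 1 copy silent in each cell, had the fewest peaks per gene. Of 948 X-linked coding genes 384 had a promoter peak (40.5%), against 12335 of 20807 autosomal ones (59.3%, log2 odds −1.10, Fisher's exact test p 8.09e-30). The X held 1.12 peaks per coding gene and 6.23 per Mb, and ranked last of 20 chromosomes in both. Chromosome 12 had the most per gene (5.26) and chromosome 11 the most per Mb (41.7). The log2 odds were −1.06 with the pool I list and −1.15 with the pool J list. All 5 coding genes of the X inactivation and escape list had a promoter peak (log2 odds 2.97, adjusted p 0.104 over 36 lists, Fisher's exact test), with the escape genes Ddx3x (signal 25.4), Eif2s3x (signal 16.3) and Kdm5c (signal 13.9) the highest. Of the non-coding genes of the inactivation centre, Ftx had a signal of 15.0, Jpx 8.21 and Xist, which coats the silent X, 7.36, and Tsix had no promoter peak.

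**Figure D3:**
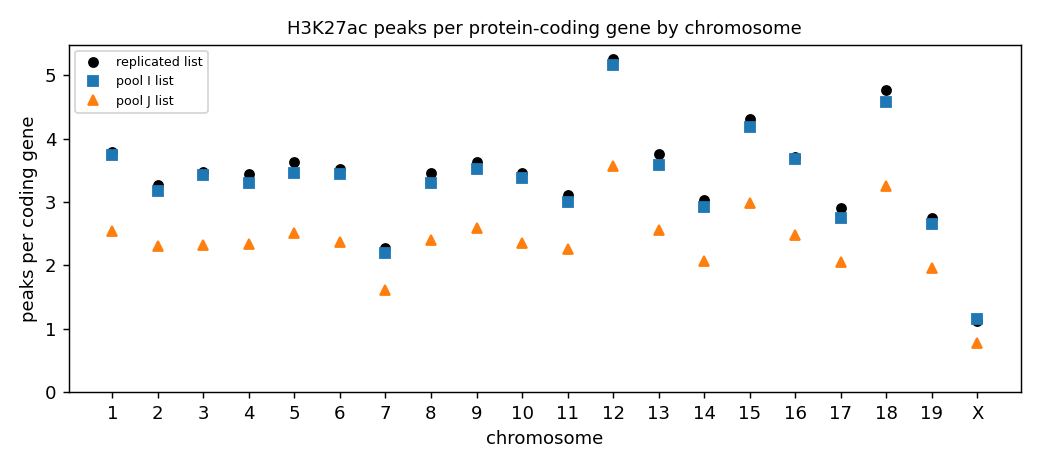
Number of H3K27ac peaks per protein-coding gene on each chromosome in the replicated, pool I and pool J lists. The X chromosome had 1.12 in the replicated list, the lowest of 20, and chromosome 12 had 5.26, the highest.

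At the summits of the 52300 distal peaks, 3 of the 16 motifs differed from the flanks. SOX sites, bound by factors of neural progenitors and glia, were in 7.53% of summits and 6.94% of flanks (log2 ratio of discordant pairs 0.13, adjusted p 0.00176). Sites of MEF2, a factor of activity-dependent transcription in neurons, were fewer at summits (2.22% against 3.64%, log2 ratio −0.74, adjusted p 1.75e-41), as were those of CTCF, which anchors chromatin loops (0.0688% against 0.132%, log2 ratio −0.93, adjusted p 0.00885). These are McNemar's exact tests over 16 motifs. Summits had a mean GC content of 48.4% and flanks of 45.3%. Against flanks of matched GC content, the MEF2 difference was gone (log2 ratio 0.01) and SOX was not called (log2 ratio 0.09, adjusted p 0.321). CTCF kept its call (log2 ratio −1.52, adjusted p 0.00326, McNemar's exact tests). It rested on few peaks, 15 with a site at the summit alone against 44 in the flank alone among 24471. Without GC matching these were 36 against 69 of the 52300. Flanks were not checked for lying in the same or another peak. The summits are those of a histone mark and not of factor binding. Fewer sites near them do not show that the whole peak held fewer sites. At a −log10 q of at least 5, SOX (log2 ratio 0.13, adjusted p 0.0875) and CTCF (−1.02, adjusted p 0.0875, McNemar's exact tests) were not called.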

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

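The 2 alternatives that match genes on promoter CpG content and the test without multicopy families were chosen after the result was seen, and the others were set beforehand and all were run. Each result was recomputed with 1 choice changed, except that leaving out a pool also replaced the replicated by a pseudoreplicated list. Of the comparisons with the reported value, 959 kept direction and side of the threshold or, without a test, stayed within a set tolerance. Among these, 4 tested values were exactly 0 and had no direction. The tolerance for overlap shares was wide. A fall from 55.5% to 35.8% of pool I peaks matched, under reciprocal overlap, counted as kept. A further 78 lost a call, 19 gained one, 66 turned in direction and 10 values without a test moved. Of those that turned, 58 were called in neither setting. These counts leave out the main value of each kind of result. Among those left out are the number of replicated peaks, the share of pool J peaks matched, genes with a promoter peak, large domains and the X chromosome. Several of these main values also moved and are given below. The causes were not tested except where stated.

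The gene lists called at distal peaks numbered 4 to 5 higher, against 5, and 1 lower, against 1, under each alternative run. The X chromosome kept its lower share of genes with a promoter peak. The log2 odds were −1.15 to −1.06 over the promoter windows, the stricter q, the list of both pools and each pool alone. They were in the same range without the multicopy families defined below, −0.79 within deciles of CpG ratio and −0.65 with both.

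By construction, the number of peaks per list was lower at a −log10 q of at least 5 (38593), among those at or above the median signal (36566) and when intervals within 1000 bp were joined (44213), against 72027. Reciprocal overlap of at least 50% left 50.2% of pool J peaks matched, and overlap of at least 50% of the shorter peak 91.7%, against 93.1%. Genes with a promoter peak came to 55.9% with the gene's 5′ end only, 54.8% at the stricter q, 54.2% among peaks at or above the median signal and 55.2 to 58.2% without 1 of the pools, against 58.5%. Large domains numbered 755 with stitching within 5000 bp and 2230 with no stitching, against 497.

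Promoter lists called higher numbered 8 at the stricter q and 0 among only genes with a peak (0 at an unadjusted p under 0.05), against 13. They numbered 10 with the gene's 5′ end only, 8 to 12 without 1 of the pools and 15 with the 2500 bp window. Lists called lower numbered 5 among only genes with a peak (10 at an unadjusted p under 0.05), against 13. They numbered 12 with the gene's 5′ end only, 13 to 15 without 1 of the pools and 14 with the 2500 bp window. A promoter peak alone brings a gene into the set of only genes with a peak, where 87.7% of genes outside the excitatory neuron list had one, so the calls that end there, which include all 13 higher ones, say nothing on stability. Lists with lower promoter signal numbered 4 by peak width in place of signal, 4 when matched on promoter CpG content and 4 to 7 without 1 of the pools, against 9. Domain lists numbered 2 with the pseudoreplicated list of both pools 1 to 3 without 1 of the pools and 6 with promoter peaks kept, against 4. Motifs higher at summits numbered 0 against flanks matched on GC content and 0 at the stricter q (0 and 2 at an unadjusted p under 0.05), against 1, and motifs lower 1 in both, against 2.

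At a −log10 q of at least 5, the values that turned were the intron share (36.3%), promoter log2 odds of interneurons (−0.75) and endothelial cells (−0.72), distal differences of endothelial cells (−0.134) and the interferon response (−0.0732), domain differences of deep layers (−5.53) and housekeeping genes (11.2), and AP-1 (−0.0548) and CRE (−0.0813). Among only genes with a peak, promoter log2 odds turned for deep layers (−0.11), oligodendrocytes (−1.34), striatum (−0.17) and imprinted genes (−0.68), and with the 500 bp promoter window for striatum (−0.0664). By peak width in place of signal, differences turned for upper layers (33.8), astrocytes (15.1), oligodendrocyte precursors (2.88), striatum (0.991), hypothalamus (3.14), neurogenesis (37.2) and heat shock genes (−5.49).

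Distal differences turned within 50 kb for endothelial cells (−0.173) and the interferon response (−0.121), within 250 kb for endothelial cells (−0.0716), striatum (−0.532) and the interferon response (−0.0242), by summed distal length for endothelial cells (−207.6) and with the list of both pools for the interferon response (−0.220). Against flanks matched on GC content, log2 ratios turned for MEF2 (0.00536), EGR (−0.52), NEUROD (−0.0746), NFI (−1.22) and OCT/POU (0.23), within 50 bp of the summit for AP-1 (−0.0150) and CRE (−0.0888) and with flanks 2000 to 2200 bp away for CRE (−0.41).

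Domain differences turned with no stitching for astrocytes (−2.01), oligodendrocytes (−4.24), oligodendrocyte precursors (4.67), meningeal fibroblasts (4.66), housekeeping genes (27.5), patterning factors (11.9), hypothalamus (4.66), germline (18), imprinted genes (1.33) and X inactivation (34.7), and with stitching within 5000 bp for astrocytes (−0.103), oligodendrocytes (−1.22) and housekeeping genes (7.52). With promoter peaks kept they turned for interneurons (0.180), oligodendrocytes (−0.441), their precursors (3.39), housekeeping genes (10.97), patterning factors (10.97), muscle (−5.71), neurogenesis (6.80) and heat shock genes (5.41), and by summed width alone for oligodendrocytes (−0.0346).

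Between the list without pool I and the list without pool J, the values that turned ranged from −0.0689 to 1.03 for interneurons and −0.30 to 0.31 for striatum at promoters, −0.318 to 0.749 for endothelial cells, −0.109 to 0.270 for the interferon response and −0.126 to 0.533 for oligodendrocyte precursors at distal peaks, −6.03 to 8.54 for imprinted genes in promoter signal, and −5.00 to 43.4 for housekeeping and −5.01 to 2.91 for receptor genes in domains. The last 2 of the distal results turned without pool J and the others without pool I.

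Depth was not known for either pool, so a region missing from a list may lie below its detection limit, and the 31099 pool I peaks with no match in pool J had a median percentile of 25.8. No paired analysis was possible because there was a single group.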

Other observations

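The tests on multicopy families, on the sensitivity of pool J, on the astrocyte and microglia lists alone and on a smaller share of cells, as well as the expected counts from CpG content, were chosen after the result was seen. Promoters rich in CpG dinucleotides carried the mark in most cases, from 6.12% of genes in the lowest decile of CpG ratio to 95.3% in the highest, and some lists lay far from what CpG content gives. From CpG content 30.6 of the 39 Hox genes and 13.5 of the 20 midbrain and hindbrain genes would have had a promoter peak, and 0 and 1 did. Of the 14 neurogenesis and proliferation genes 11.8 would have had one and 7 did, of the 14 germline genes 8.39 and 1 did, of the 12 choroid plexus and ependymal genes 5.48 and 1 did, and of the receptor genes 163 and 11 did. For liver (3.52 against 1), erythroid (2.10 against 1) and lymphoid genes (2.67 against 0), CpG content already gave few. In the other direction, 18 excitatory neuron markers had one against 11.04, 16 postsynaptic genes against 9.37, 18 astrocyte markers against 10.7 and 10 microglia markers against 6.49. CpG content already gave most for oxidative phosphorylation (14.3 against 16), clock (13.6 against 16), activity-regulated (16.3 against 20) and housekeeping genes (14.4 against 18). It also did so for presynaptic (14.1 against 18), heat shock (8.7 against 11), deep layer (13.1 against 16) and upper layer genes (10.8 against 14). These counts carry no test.

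Some lists stood differently by width and by signal, while the excitatory, presynaptic, postsynaptic and clock lists were called higher by both the interneuron, endothelial, interferon and receptor lists lower by both, and the channel and activity-regulated lists higher by width alone. Ranked by width, upper layer markers stood 33.8 points above all genes with a promoter peak (adjusted p 0.00699 over 26 lists, permutation test), against −13.4 by signal (adjusted p 0.303), and neurogenesis genes 37.2 points (adjusted p 0.0326, permutation test), against −25.1 by signal (adjusted p 0.173, permutation tests). Of the imprinted non-coding genes, Meg3 had a promoter signal of 10.6 (13.7 in pool I and 8.91 in pool J), Kcnq1ot1 6.36 and Airn 2.87, the last with no promoter peak in pool J, and H19 and Rian had none. The pool I list held 1 peak on the Y chromosome (90732124–90732615, signal 2.32, rank 69224 of 69835), although the mice were female.

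Fewer X-linked than autosomal genes had a promoter peak. Genes with symbols that begin with Olfr, Or and a digit, Vmn, Gm or Rhox were left out as multicopy families, whose reads map poorly. Without them the log2 odds were −1.11, so these genes are not the whole cause. Families with other names stayed in, and the Gm symbols can include single-copy genes, so multicopy families in general stay open. Promoter CpG content is not the whole cause either, since within its deciles the log2 odds were −0.79 (95% interval −1.03 to −0.54). With both applied the log2 odds were −0.65 (95% interval −0.90 to −0.39), so that the genes left out and CpG content together leave part of the difference. Lower signal because 1 copy is silent may be part of it, since X-linked promoters with a peak had 0.766 times the median signal of CpG-matched autosomal ones (permutation p 1e-04, the smallest that 10000 resamples can give). Other differences between X-linked and autosomal genes, such as expression restricted to other tissues, stay open, and no biological explanation was tested between groups, since there was 1 group.

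The pool J list held fewer peaks than the pool I list. Lower sensitivity of the pool J data may be part of this, but the ranks cannot decide it. Pool I peaks with no match in pool J had a median signal percentile of 25.8 in pool I. Pool J peaks with no match in pool I were low as well, at 18.4 in pool J. A low rank of unmatched peaks thus does not single out pool J. Different cell makeup of the pools cannot be told apart from lower sensitivity. Of 10 cell type lists, 0 shifted in promoter signal rank at an adjusted p under 0.05 (2 at an unadjusted p, permutation tests). The largest shift was −8.60 points, for excitatory neuron markers, and few genes stood in each list. No biological explanation was tested between groups, since there was 1 group.

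Marked promoters of the 5 lists of glial, vascular and interneuron genes had low signal, and these lists were not alone in this. Forebrain patterning factors were also called below CpG-matched genes (−34.4 points, adjusted p 0.0202, permutation test over 26 lists). After matching, 4 lists were called lower and 5 higher. Promoter CpG content is not the whole cause, since 3 of the 5 lists were still called below CpG-matched genes. These were interneuron (−37.0 points, adjusted p 0.00251), oligodendrocyte (−31.1, 0.0226) and endothelial markers (−32.7, 0.0200, permutation tests over 26 lists). For the astrocyte and microglia lists alone, both still lay lower but 0 of 2 were called (adjusted p 0.0939 and 0.142, permutation tests). Their differences were −22.0 and −24.4 points against −32.5 and −40.2 before matching, so promoter CpG content stays open. A smaller share of these cells in the tissue might lower the signal, but 0 of the 5 lists had fewer distal peaks than matched genes at an adjusted p under 0.05. The lists went both ways, with 2.00-fold for oligodendrocyte (unadjusted p 0.0336), 1.88-fold for astrocyte, 1.03-fold for endothelial, 0.661-fold for microglia and 0.512-fold for interneuron markers (permutation tests), so this cannot be told apart. No biological explanation was tested between groups.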
